A study of Rhizophagus irregularis DAOM 181602=DAOM 197198 with 30 samples.

How the data were processed

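Messenger RNA selected by its poly-A tail was sequenced by the authors, as paired reads on an Illumina instrument, from germinating spores of the arbuscular mycorrhizal fungus Rhizophagus irregularis. The labels give 30 samples in 10 groups. Of these, 25 have a column in the 5 tables used here. The other 5 samples (acetone 1 h replicate 1, GR24 2 d replicate 2, GR24 7 d replicate 1, acetone 7 d replicate 3 and replicate 3 of the controls titled as without roots) have no column there and were not analysed here. Samples were assigned to groups by their titles and treatment fields. In the root table the column headings name the 2 groups the other way round. The titles were followed, the groups are called by their titles throughout, and every direction of that comparison reverses if the column headings are right. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples.

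Each table lists the same 30282 gene models of the JGI catalogue Gloin1. Per the file headers, each library has total gene reads, a read count in which reads matching several models are included, and unique gene reads, a read count of reads matching 1 model. The deposited RPKM values (reads scaled by model length and library size) were made by the authors from the total gene reads, and the total that each library's RPKM implies equalled its sum of total gene reads. Per the file headers, the remaining deposited columns are the gene length in bases, a signed fold change of weighted proportions, which is a score of the authors' comparison, and a p-value of Baggerley's test corrected by the authors to a false discovery rate. The alignment tool and its version are not given in the sources used here. No genome was used here, and the tables used here give no coordinates, so genes are named by protein ID and by the description in the tables. A best-hit title was present for 14093 models and a functional description for 14305. None of the protein IDs was paired with a locus of the reference gene table, which belongs to another assembly. The 7154 models with no read in any library stayed in the tables but could not be tested.

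Depth ran from 5786080 to 11812317 gene reads per library. Ratios against a group with 1 to 3 reads have a 95% exact binomial interval, and folds against a group with 0 reads are lower bounds taken at a floor of 3 reads over the group. Both cover counting error only, because reads without molecular identifiers are not independent molecules.

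Total gene reads were tested with edgeR 4.0.16 in R 4.3.3 by a 2-sided quasi-likelihood test (filterByExpr by group, TMM scaling, robust fit) and adjusted by the Benjamini-Hochberg method at 0.05. Each of the 5 treatment comparisons was fitted on its own libraries. A further fit of the 20 time-course libraries tested a GR24 effect shared by the 4 times and the interaction of GR24 with time. Another tested acetone controls at 14 d against 1 h, and another tested the root effect minus the GR24 effect at 14 d. Log2 fold changes carry their standard error, and levels are TMM-scaled CPM values with the SD over the group's libraries. Replicate numbers did not pair the samples at 14 d, where, after group means were taken out, the correlations across genes between equal numbers were 0.0214, -0.0438 and -0.0071. In the other comparisons a group had only 2 libraries, whose deviations mirror each other, so this check cannot decide there. At 2 d the values between equal numbers were -0.1309 and 0.0202. Libraries of a group were checked for duplicates, and none of 20 pairs was one, since their chi-square per degree of freedom lay between 2.659 and 9.092 where resampled reads would give 1. The pipeline was tested on simulated data with these group sizes, where 3.3% to 8.9% of edgeR calls were false. Of genes changed 2-fold, 89.6% to 98.5% were recovered in the 5 treatment comparisons, 100% for the shared effect, 97% for the controls over time, 83.6% for the root effect minus the GR24 effect and 77.6% for the interaction. Changes were placed only in genes with a mean of at least 5 CPM, so recovery among genes with fewer reads was not measured.

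The comparisons, the 32 gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Lists were made by keywords in the gene descriptions and tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 32 lists within each comparison. Camera with an estimated correlation and fry, which tests whether a list's members move 1 way on balance, were run beside it. With the preset correlation 34 of 192 list tests passed. With an estimated correlation 0 of 192 did, against 19 at an unadjusted p under 0.05, and fry passed 6 lists at 1 h, 3 at 2 d, 0 at 7 d, 1 at 14 d, 13 for roots and 7 across times. Unintended members drawn in by keywords were seen in 6 lists: the crinkler and secreted effector list holds mostly HSP70 chaperones, the cytoskeleton list mostly kinases described as Cdc42-related, the non-fungal keyword list mostly immunoglobulin-fold proteins, the ribosome biogenesis list many p130 nucleolar repeats, the translation factor list argonaute proteins, and the cytosolic ribosomal protein list mitochondrial ribosomal proteins, ubiquitin genes and proteins that share a domain name. These were kept as written and also tested without those members. Lists of mitochondrion-encoded models and of nuclear-encoded respiratory chain members were added after the data were seen.

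Genes named in the text follow a rule. Among genes past the threshold, with every treated library above or below every control library and at least 5 CPM in the higher group, it takes the 10 largest rises and 10 largest falls with a described function. It adds 2 in each direction whatever their description, the 3 members with the smallest p of each passing list in that list's direction, and any gene that the tables name SIS1, SP7, MST2, or as a phosphate or ammonium transporter. For the controls over time it takes 5 in each direction. Names outside the rule are stated as such.

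Alternatives were RLE size factors, DESeq2 1.42.0, limma-voom, no filter on low counts, a strict filter (a mean of 50 reads and 1 CPM in 3 libraries), the replicate number as a block, unique gene reads, all libraries in 1 fit, and leaving out each library, replicate number or time. Leaving out models that carry multi-match and mitochondrial reads was added after the data were seen, as was the root effect minus the GR24 effect with the root direction of the column headings. Where a library was left out and its group kept 1 library, that library is assumed to vary like the other groups. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.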

Results

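Gene expression was measured by RNA sequencing in germinating spores of Rhizophagus irregularis, a fungus that lives in symbiosis with plant roots and feeds them phosphate. In the time course, spores germinated for 2 d received GR24, a synthetic strigolactone, at 1e-06 M, or acetone diluted 1 in 1000. Strigolactones are hormones that plant roots release. Cultures of 80000 spores were taken after 1 h, 2 d, 7 d and 14 d. In a separate set, 60000 spores on cellophane were kept for 14 d over carrot hairy roots or without roots. The libraries with counts numbered 3 GR24 against 2 acetone at 1 h, 2 against 3 at 2 d, 2 against 2 at 7 d and 3 against 3 at 14 d. The root set had 3 libraries titled root exudates and 2 titled controls. Gene reads per library ran from 5786080 to 11812317, a depth at which 13967 to 14752 gene models per comparison had enough reads to be tested. Below, ± after a log2 fold change is its standard error, and ± after a CPM value is the SD over the libraries of a group.

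**Figure D1:**
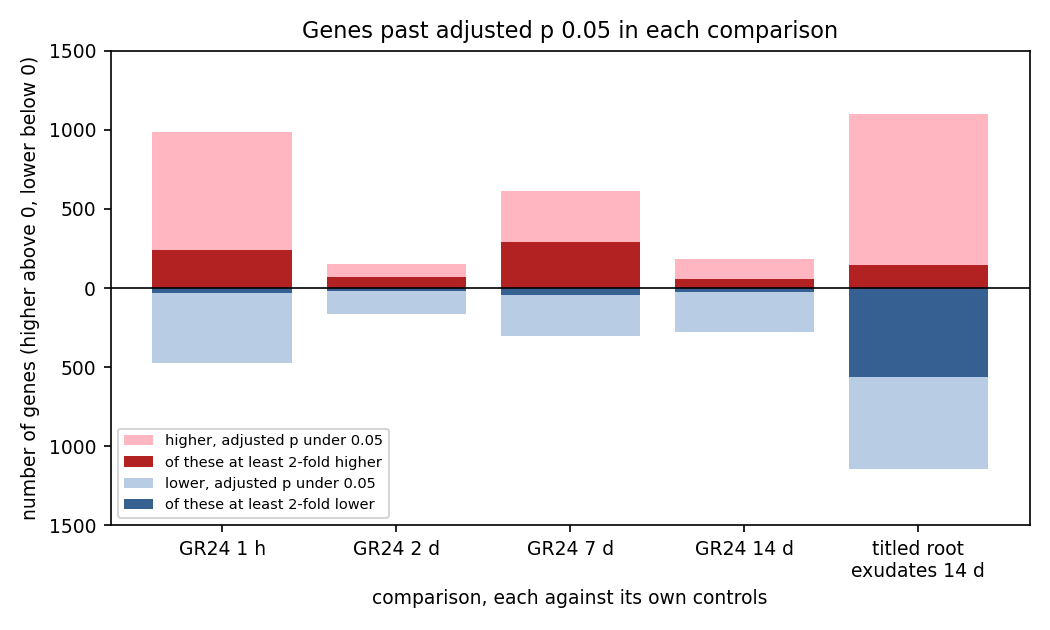
Number of gene models past an adjusted p of 0.05 (edgeR quasi-likelihood) in each comparison, higher above 0 and lower below 0, with darker bars for those changed at least 2-fold. GR24 gave 985 higher and 474 lower models at 1 h and 182 higher and 275 lower at 14 d, and the libraries titled root exudates gave 1101 higher and 1144 lower.

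The first comparison asked how spores respond within 1 h of GR24 (n = 3 against 2). A chitin synthase model (protein ID 67965), whose description also names a cytochrome b5 domain, rose from 1.11 ± 0.128 to 62.6 ± 2.19 CPM (log2 fold change 5.81 ± 0.198, adjusted p = 3.45e-19). Chitin synthases make the cell wall polymer chitin. Of the 10 largest rises with a described function, 6 were type 11 methyltransferases, enzymes that transfer methyl groups from S-adenosylmethionine. Among them, 25998 rose by 5.65 ± 0.197 and 20845 by 5.51 ± 0.189 on the log2 scale, the latter to 474 ± 75.5 CPM. The methyltransferase 22150 had 166 reads with GR24 and 0 in the controls, at least 36.5-fold higher. An alpha/beta hydrolase described as an arylacetamide deacetylase (346819) rose from 10.1 ± 0.541 to 285 ± 11.6 CPM.

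Many genes of detoxification and export rose at 1 h. In the cytochrome P450 and glutathione S-transferase list, whose enzymes oxidise or conjugate small hydrophobic molecules, 52 of 161 members rose, 6 fell and 103 did not pass (adjusted over the list alone, 59 rose and 10 fell). By camera the list had an adjusted p of 7.92e-09, and adjusted p = 0.231 with an estimated correlation. The P450 model 347608 went from 1079 ± 99.5 to 7684 ± 64.1 CPM, and the P450 models 345274 and 19698 rose by 3.60 ± 0.106 and 2.26 ± 0.087. In the ABC and multidrug transporter list, membrane pumps and facilitators, 31 of 108 rose, 2 fell and 75 did not pass (adjusted over the list alone, 34 and 3; adjusted p = 3.71e-06, adjusted p = 0.300 with an estimated correlation). The ABC transporter 290312, described as of the breast cancer resistance protein type, rose from 299 ± 6.2 to 1162 ± 51.1 CPM. The facilitator 3690 rose by 2.12 ± 0.093 and the drug resistance protein 193343 by 2.26 ± 0.09.

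Among chaperones, which help proteins fold, more members fell than rose at 1 h, while most did not pass. In the heat shock and chaperone list 17 of 254 members fell, 6 rose and 231 did not pass (adjusted over the list alone, 16 and 5; adjusted p = 0.0274, adjusted p = 0.231 with an estimated correlation). The Hsp90 co-chaperone Cdc37 model (339577) changed by -0.72 ± 0.075 and a DnaJ-domain model (349359) by -1.03 ± 0.114. The largest other falls with a described function included a ubiquitin model (68287, -1.86 ± 0.235, adjusted p = 9.87e-07), an EF2 kinase family model (20914, -1.37 ± 0.196) and a laminin-like model (348578, -1.31 ± 0.122). A LAG1-type transcription factor model (343820) was lower as well, at 51.1 ± 14.3 CPM against 235 ± 14.6 (adjusted p = 0.0157). That call ended without either acetone library, with log2 fold changes of -2.27 and -2.15.

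By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 1459 of 13967 models passed at 1 h, 985 higher and 474 lower, and 276 of them changed at least 2-fold, 242 upwards. The count was 813 without acetone replicate 2 and 689 without replicate 3, and 22 of the 31 named genes passed in every fit that left out 1 library. Without acetone replicate 2 the methyltransferase 25998 rose by 6.42.

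After 2 d (n = 2 against 3), the question was what stays changed while the spores keep germinating. The chitin synthase model 67965 was at 23.5 ± 3.06 CPM against 0.345 ± 0.245 (6.20 ± 0.325). The methyltransferase 20845 rose by 3.52 ± 0.189, the hydrolase 346819 by 2.93 ± 0.204 and the P450 models 345274 and 347608 by 2.65 ± 0.189 and 2.58 ± 0.076. A RING-type zinc finger model described as a predicted E3 ubiquitin ligase (350230), a kind of enzyme that marks proteins with ubiquitin, went from 84.0 ± 8.04 to 450 ± 5.79 CPM (adjusted p = 1.07e-11). The conserved hypothetical protein 95868 rose from 6.20 ± 1.18 to 83.7 ± 16.9 CPM. Downwards, a short model resembling an unconventional myosin (35042) went from 68.7 ± 4.21 to 21.3 ± 1.69 CPM (-1.70 ± 0.124), and the P450 model 4393 changed by -1.12 ± 0.105.

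Of the lists at 2 d, the ABC and multidrug transporters had 11 of 109 members higher, 0 lower and 98 not past the test by edgeR (7 lower at an unadjusted p under 0.05, 0 lower by DESeq2 and by limma-voom). It had 12 higher and 1 lower adjusted over the list alone, with adjusted p = 0.0222 by camera and adjusted p = 0.529 with an estimated correlation. The drug resistance protein 193343 rose by 0.76 ± 0.113, and the multidrug resistance protein 6100 by 2.10 ± 0.316, a call that ended without GR24 replicate 3 at 2.06. In the oxidative phosphorylation list 6 of 83 rose and 77 did not pass (adjusted over the list alone, 21 higher and 1 lower; adjusted p = 0.000414, adjusted p = 0.273 with an estimated correlation). All 6 are encoded in mitochondrial DNA, among them NADH dehydrogenase subunit 5 (334389, 6.18 ± 1.37 to 21.5 ± 0.377 CPM) and apocytochrome b (38829, 1.78 ± 0.197). Of the 69 nuclear-encoded members, 0 rose by edgeR (16 at an unadjusted p under 0.05; 0 by DESeq2 and by limma-voom), and adjusted over the list alone 8 were higher and 1 lower. The share of reads matching several models, of which 39.4% and 39.2% lie in 2 models, was 0.798 ± 0.012% with GR24 and 0.374 ± 0.0748% in the controls at 2 d.

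**Figure D2:**
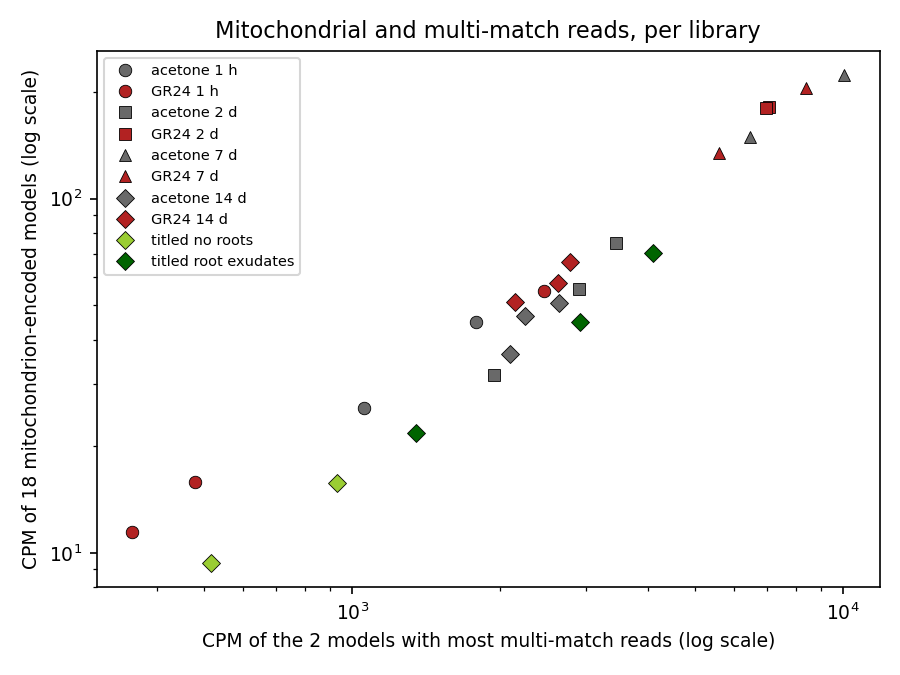
Summed CPM of 18 mitochondrion-encoded models (vertical, log scale) against the CPM of the 2 models that hold most multi-match reads (horizontal, log scale), 1 point per library. The GR24 2 d libraries lie with the 7 d libraries at the upper right, with means of 181 CPM for GR24 2 d against 54.1 for acetone 2 d.

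The remaining lists that passed at 2 d moved by small amounts. Nitrogen uptake and metabolism had 2 of 68 members higher, the nitrate transporter 30566 (0.77 ± 0.155) and the nitrite reductase 3357 (0.49 ± 0.107), both steps of nitrate assimilation. Both calls ended without GR24 replicate 3 (0.615 and 0.40) or acetone replicate 3 (0.84 and 0.50). Adjusted over the list alone it had 8 higher and 2 lower (adjusted p = 0.0200, adjusted p = 0.529 with an estimated correlation). In the cytosolic ribosomal protein list 3 of 166 rose and 1 fell, by either adjustment (adjusted p = 0.0203, adjusted p = 0.529 with an estimated correlation). The ubiquitin and S27a fusion model 22168 rose by 0.63 ± 0.084. The S4 model 50295 and the S13 model 11828 rose as well, but their calls ended without acetone replicate 3 (0.43 and 0.34). Without GR24 replicate 3 their values were 0.39 and 0.235. Repeat proteins of the Sel1, BTB and kelch types had 14 of 1095 members lower and 2 higher (adjusted over the list alone, 12 and 1; adjusted p = 0.0290, adjusted p = 0.441 with an estimated correlation). The kelch model 15897 was among them, at -0.58 ± 0.084. The members 26418 and 33301 were lower too, at -0.40 and -0.66 without GR24 replicate 3. The call of 33301 ended without acetone replicate 3 (-0.65). The list of the TCA and glyoxylate cycles passed upwards with 0 of 30 members past the test by edgeR, DESeq2 or limma-voom, adjusted over all genes or, with edgeR, adjusted over the list alone. At an unadjusted p under 0.05, 8 members were higher (list adjusted p = 0.0222, adjusted p = 0.529 with an estimated correlation). The DNA replication and cell cycle list passed upwards (adjusted p = 0.0200, adjusted p = 0.529 with an estimated correlation). By edgeR, DESeq2 and limma-voom alike 0 of its 128 members were higher and 1 lower, and 18 were higher at an unadjusted p under 0.05.

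In all, 316 of 14704 models passed at 2 d, 150 higher and 166 lower, and 87 changed at least 2-fold (29 without GR24 replicate 3, 43 without acetone replicate 3 and 139 without acetone replicate 1). The count fell to 46 without GR24 replicate 3 and to 70 without acetone replicate 3, and 16 of the 39 named genes passed in every fit that left out 1 library.

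At 7 d (n = 2 against 2) the histones and the genes of DNA replication and cell division stood out. In the histone list 14 of 48 members rose, 0 fell and 34 did not pass by edgeR (0 lower at an unadjusted p under 0.05, by DESeq2 and by limma-voom). The counts were the same adjusted over the list alone (adjusted p = 1.41e-10, adjusted p = 0.805 with an estimated correlation). Histone H4 (29938) went from 124 ± 7.68 to 301 ± 19.8 CPM, histone H2B (340364) from 261 ± 19.6 to 582 ± 50.3 and histone H3 (29937) rose by 1.37 ± 0.1. In the DNA replication and cell cycle list 42 of 128 rose, 1 fell and 85 did not pass (adjusted over the list alone, 46 and 3; adjusted p = 2.81e-15, adjusted p = 0.442 with an estimated correlation). The condensin subunit D2 model (84059), part of the complex that compacts chromosomes, rose by 1.44 ± 0.129 (adjusted p = 2e-12). The large and small subunits of ribonucleotide reductase (343286 and 80358), which makes the building blocks of DNA, went from 61.4 ± 1.85 to 133 ± 4.83 CPM and from 36.3 ± 0.467 to 82.0 ± 5.96 CPM.

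**Figure D3:**
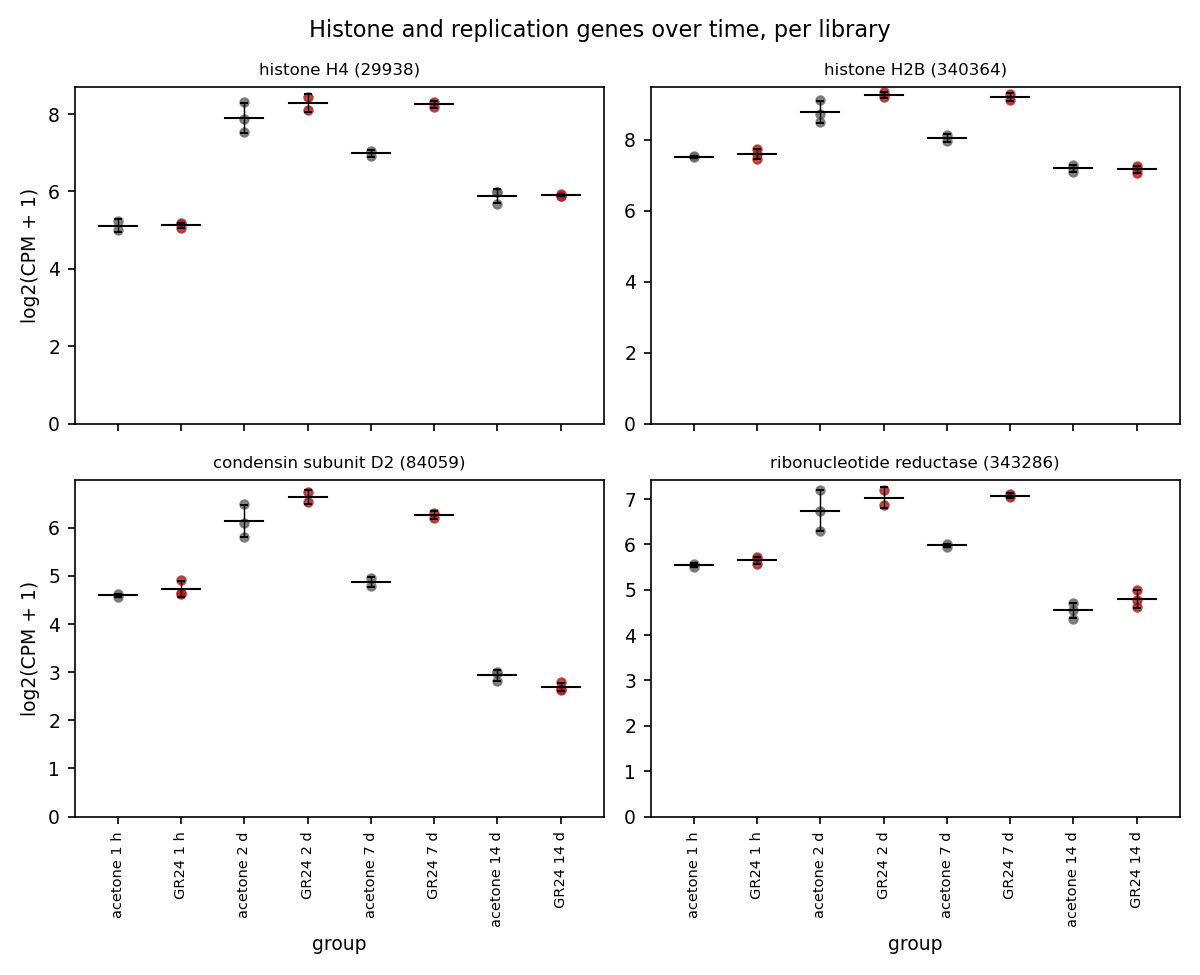
Levels of histone H4, histone H2B, condensin subunit D2 and the large subunit of ribonucleotide reductase in the 8 time-course groups, as log2(CPM + 1), 1 point per library with the group mean ± SD. At 7 d both GR24 libraries lie above both acetone libraries in each panel.

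Some single genes outside the lists that passed had large rises at 7 d. The chitin and cell wall glucan list had 4 of 97 members higher and 2 lower (adjusted over the list alone, 4 and 5; adjusted p = 0.182). Its member 67965, the chitin synthase model, was at 55.4 ± 0.497 CPM against 0.827 ± 0.805 (6.40 ± 0.286). A model with a LysM domain (349023), which binds chitin and related sugars, was at 19.2 ± 3.79 against 0.564 ± 0.19. A collagen-like model (347597) rose by 4.82 ± 0.366, a class V aminotransferase (3482) by 4.56 ± 0.356 and a rhodopsin-like G protein-coupled receptor (326783) by 3.33 ± 0.314. The acetone libraries at 2 d had 17.3, 49.2 and 35.5 CPM of 349023 and 16.4, 39.2 and 28.1 CPM of 347597. Neither of these models was above its acetone 2 d range with GR24 at 7 d. Without acetone replicate 1 and 2 the log2 values were 7.67 and 5.29 for 67965, 6.10 and 3.72 for 347597, and 5.25 and 3.76 for 3482.

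The P450 and glutathione S-transferase list was lower on balance at 7 d, with 23 of 163 members lower, 12 higher and 128 not past the test (adjusted over the list alone, 32 and 16; adjusted p = 0.00680, adjusted p = 0.805 with an estimated correlation). The P450 models 317811, 4393 and 6900 changed by -0.68 ± 0.083, -0.83 ± 0.108 and -0.60 ± 0.084, while 345274 rose by 3.40 ± 0.264. A UDP-glucosyltransferase family model (234774) went from 21.7 ± 1.29 to 6.71 ± 0.265 CPM. An O-acetylhomoserine aminocarboxypropyltransferase (276270), an enzyme of sulfur amino acid synthesis, changed by -1.47 ± 0.232, and the myosin-like model 35042 by -1.37 ± 0.126. In the trehalose and glycogen list, reserve sugars of fungal spores, 3 of 18 members fell and 15 did not pass (5 fell adjusted over the list alone; adjusted p = 0.00680, adjusted p = 0.805 with an estimated correlation). These were a glycogen debranching enzyme (256952, -0.30 ± 0.082), a trehalose-6-phosphate synthase (28707, -0.28 ± 0.083) and a glycogen phosphorylase (78197, -0.26 ± 0.082). These 3 calls ended without GR24 replicate 2 and without either acetone library, at -0.23, -0.24 and -0.21 without the GR24 library, at -0.30, -0.305 and -0.30 without acetone replicate 1 and at -0.30, -0.27 and -0.22 without acetone replicate 2. The list of cytosolic ribosomal proteins passed upwards with 3 of 166 members (adjusted p = 0.0418, adjusted p = 0.906 with an estimated correlation), the same 3 adjusted over the list alone. Of these, 39935 is the replication licensing protein MCM6 (0.61 ± 0.105), 341234 a bacterial-type ribosomal protein S12 (0.86 ± 0.208) and 348204 a CDC25-type exchange factor for Ras-like proteins (0.35 ± 0.099). Without members other than those described as 40S or 60S ribosomal proteins, 78 were left, with 0 past the test by edgeR, DESeq2 and limma-voom, 6 higher by edgeR at an unadjusted p under 0.05, and adjusted p = 0.00544 for the list (adjusted p = 0.906 with an estimated correlation). The call of 348204 ended without GR24 replicate 3 (0.27), acetone replicate 1 (0.305) or acetone replicate 2 (0.40).

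At 7 d 917 of 14269 models passed, 615 higher and 302 lower, and 334 changed at least 2-fold, 291 of them upwards. DESeq2 gave 500, and 574 passed without acetone replicate 1, while 29 of the 36 named genes passed in every fit that left out 1 library.

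At 14 d (n = 3 against 3), the last time, the genes with the largest rises included those of single transporters and P450 enzymes beside genes already raised earlier, while the lists did not pass. The P450 and glutathione S-transferase list had 6 of 164 members higher and 19 lower (adjusted over the list alone, 18 and 27; adjusted p = 0.579). The ABC and multidrug transporters had 5 of 110 higher and 7 lower (adjusted over the list alone, 10 and 11; adjusted p = 0.960). A sugar transporter (341721) rose from 2.98 ± 0.975 to 20.3 ± 3.69 CPM (2.75 ± 0.211, adjusted p = 8.7e-08). A major facilitator protein (340471) rose from 15.2 ± 2.35 to 47.7 ± 4.76 CPM, and the multidrug resistance protein 6100 from 1.25 ± 0.785 to 8.40 ± 0.422 CPM. The P450 models 54172 and 345274 rose by 3.02 ± 0.275 and 2.88 ± 0.283, the hydrolase 346819 by 3.22 ± 0.32 and the hypothetical protein 95868 by 3.57 ± 0.268. The chitin synthase model 67965 was at 101 ± 34 CPM against 5.93 ± 0.697 (4.07 ± 0.378, adjusted p = 0.014). That call ended without any 1 of the acetone libraries 1, 2 and 3, at 4.00, 4.08 and 4.14. The aminotransferase 3482 was at 98.1 ± 25.1 against 16.1 ± 1.84 CPM (adjusted p = 0.0111), and its call ended in the same fits, at 2.54, 2.69 and 2.56.

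Downwards at 14 d, an ABC transporter of the ABC-2 type (22144) changed by -1.49 ± 0.186, and an aromatic-ring hydroxylase (14359) by -1.40 ± 0.137. An oxidoreductase of the aldo/keto reductase family (22273) changed by -1.13 ± 0.084, from 113 ± 13.2 to 52.1 ± 4.51 CPM. A cecropin-described model (344902) and a subtilisin-type peptidase (328742), a secreted protease family in many fungi, went from 14.0 ± 1.31 to 6.47 ± 0.727 and from 43.2 ± 6.3 to 21.1 ± 4.02 CPM. By camera 0 of 32 lists passed at 14 d (3 at an unadjusted p under 0.05; 0 with an estimated correlation; 1 by fry). Trehalose and glycogen genes had 6 of 18 members lower and 8 adjusted over the list alone, with an adjusted p of 0.0693 for the list. Altogether 457 of 14080 models passed, 182 higher and 275 lower, and 76 changed at least 2-fold. The count was 250 without GR24 replicate 1 and 269 without acetone replicate 3. In those and the other fits that left out 1 library, 16 of 21 named genes kept passing, and without acetone replicate 3 the log2 values of 6100 and 345274 were 3.39 and 3.51.

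The 4 times together show which genes GR24 changed throughout. At every time 15 of the 13105 models tested at all 4 times passed upwards and 1, the undescribed model 22280, downwards. In every fit leaving out 1 library 8 of these 16 kept all 4 calls. These genes were chosen after their values were seen. They include the chitin synthase model 67965, the methyltransferases 25998 and 79000, the hydrolase 346819 and the P450 models 345274, 54640 and 345126. Also among them are the multidrug resistance protein 6100 and the RING-type model 350230. The call of 67965 at 14 d ended without any 1 of the acetone libraries 1, 2 and 3, at 4.00, 4.08 and 4.14. A call of 22280 ended in fits without GR24 replicate 2 or 3 or acetone replicate 2 at 1 h, GR24 replicate 1 or 3 or acetone replicate 1 or 3 at 2 d, and any GR24 library or acetone replicate 3 at 14 d, with log2 values from -1.01 to -0.43. The log2 rise of 350230 was 2.43, 2.43, 2.10 and 1.44 at 1 h, 2 d, 7 d and 14 d (interaction adjusted p = 3.33e-08). That of 25998 was 5.65, 3.21, 3.49 and 2.21 (interaction adjusted p = 0.00241). Without acetone replicate 2 its value was 6.42 at 1 h and 4.82 at 7 d. Its call at 14 d ended without GR24 replicate 3, acetone replicate 2 or acetone replicate 3 (1.885, 1.82 and 2.00), and without acetone replicate 1 the value was 2.94. The rise of 6100 was 1.84, 2.10, 1.91 and 2.71 (interaction adjusted p = 0.502), its call ended at 2 d without GR24 replicate 3 (2.06), and at 14 d its value was 3.39 without acetone replicate 3.

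**Figure D4:**
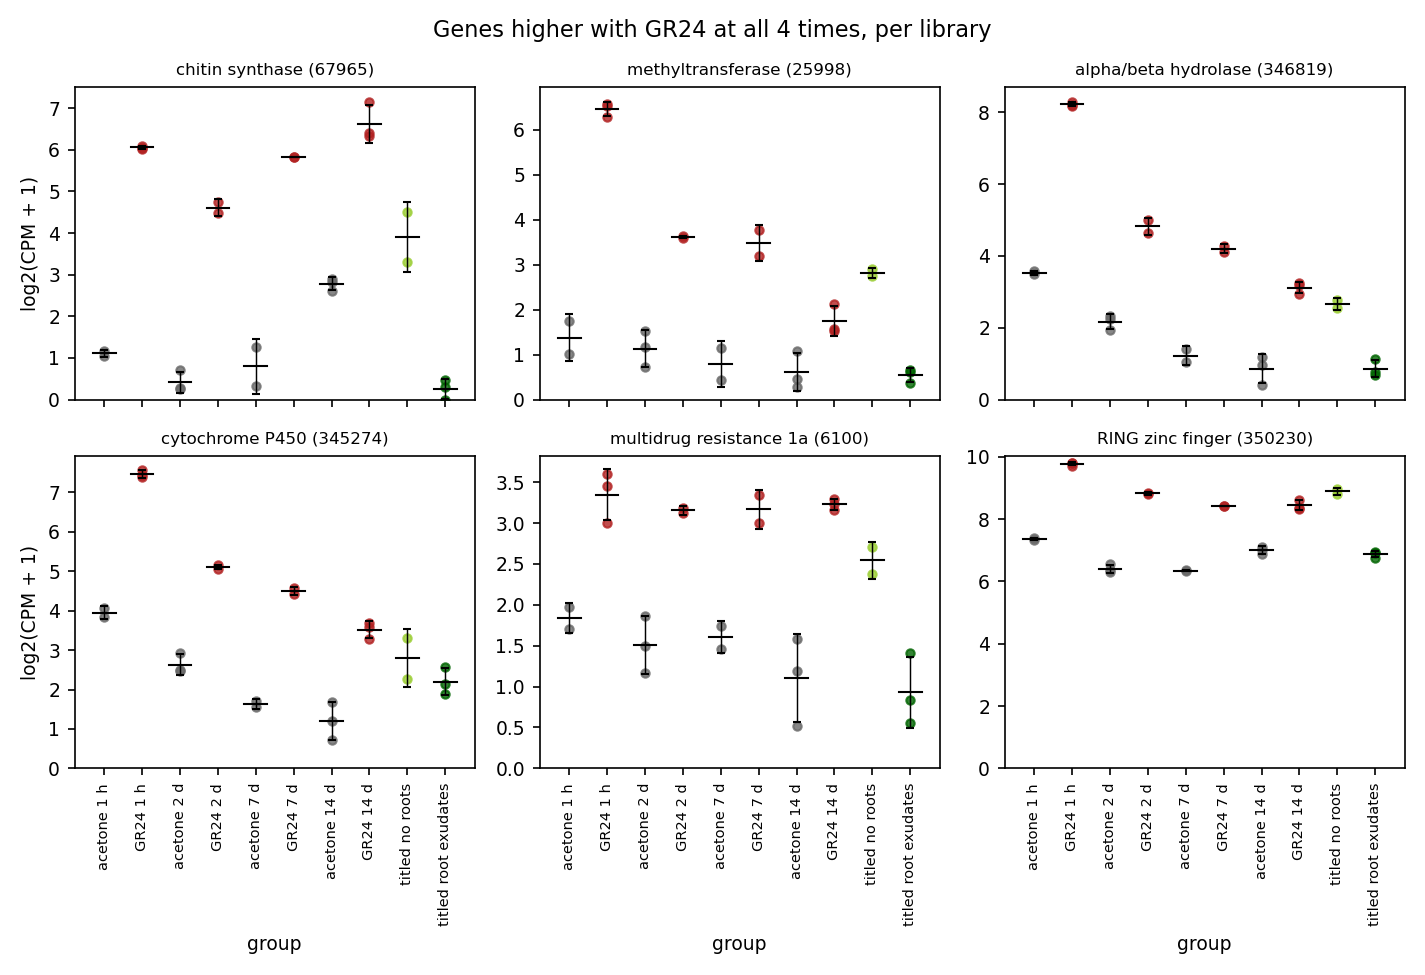
Levels of 6 described genes that GR24 raised at all 4 times, as log2(CPM + 1) in the 10 groups, 1 point per library with the group mean ± SD. For the RING-type model (350230) the log2 rise with GR24 was 2.43 at 1 h and 1.44 at 14 d, and in the root set its level was lower in the libraries titled root exudates (-2.03).

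A shared GR24 effect over the 4 times (20 libraries) was tested next. The ABC and multidrug transporters had 11 of 115 members higher and 0 lower by edgeR (3 lower at an unadjusted p under 0.05, 0 by DESeq2). It had 14 and 0 adjusted over the list alone, with adjusted p = 0.00773 and adjusted p = 0.249 with an estimated correlation. Sugar and phosphate transporters had 5 of 25 higher and 0 lower by edgeR (0 lower at an unadjusted p under 0.05 and by DESeq2). These counts held adjusted over the list alone (adjusted p = 0.0394, adjusted p = 0.122 with an estimated correlation). Heat shock proteins and chaperones had 19 of 264 lower and 3 higher (adjusted over the list alone, 22 and 4; adjusted p = 0.00628, adjusted p = 0.122 with an estimated correlation). The lipase list, which also takes in phospholipases, had 7 of 92 lower and 1 higher (adjusted over the list alone, 9 and 1; adjusted p = 0.0199, adjusted p = 0.122 with an estimated correlation). The cell cycle list had 4 of 131 higher and 1 lower (adjusted over the list alone, 12 and 2; adjusted p = 0.00251, adjusted p = 0.524 with an estimated correlation). Histones had 3 of 48 higher and 0 lower by edgeR (1 lower at an unadjusted p under 0.05, 0 by DESeq2), the same adjusted over the list alone (adjusted p = 0.00542, adjusted p = 0.249 with an estimated correlation).

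Across times 603 of 15712 models passed, 341 higher and 262 lower, and of the 99 that changed at least 2-fold (59 without the libraries of replicate 3) 98 were higher. The test of the GR24 by time interaction itself passed for 1588 models, so the size or direction of the effect differed between times for these. Without the 1 h, 2 d, 7 d or 14 d libraries the shared effect gave 837 (366 higher and 471 lower), 505, 308 and 396 models. Without all libraries of replicate 1, 2 or 3 it gave 144, 296 and 155, and without replicate 2 or 3 the interaction gave 774 and 395. Calls at neighbouring times overlapped: 69 models were higher at both 7 d and 14 d where 6.8 would be shared if calls were independent, and 102 were lower at both where 5.9 would be.

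The acetone controls show how spores change as germination goes on, from 1 h (n = 2) to 14 d (n = 3). Among the largest rises, a rhodopsin-like G protein-coupled receptor (33646), a membrane sensor family, had 183 reads at 14 d and 0 at 1 h, at least 40.8-fold higher, and a WSC-domain glycosyltransferase (98750) was at least 32.8-fold higher. A nucleoside-diphosphate sugar epimerase family model (212347) went from 0.487 ± 0.513 to 111 ± 20.6 CPM, a log2 rise of 9.58 without the libraries of replicate 2 and 6.89 without those of replicate 3. The receptor 326783, which GR24 raised at 7 d, had 328 reads at 14 d and 1 at 1 h, a ratio of 218 (95% interval 38.9 to 8650, counting error only), with a log2 change of 6.37 without replicate 2 and 9.865 without replicate 3. A hemocyanin-like model (19555) had 723 reads at 1 h and 3 at 14 d, a ratio of 362 (lower bound of the 95% interval 123, upper bound 1760, counting error only), with a log2 change of -7.635 without replicate 2 and -11.56 without replicate 3. A TRP-type ion channel (324712) went from 7.77 ± 1.49 to 0.131 ± 0.144 CPM, with a log2 change of -6.81 without replicate 3. By the same edgeR test 8236 of 15190 models passed, 4166 higher and 4070 lower, 3215 of them at least 2-fold, compared with 6149 at 2 d and 7112 at 7 d, each against 1 h.

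The root comparison asked how spores respond to roots that they do not touch (3 libraries titled root exudates against 2 titled controls), and all its directions reverse if the column headings, not the titles, are right. In the oxidative phosphorylation list 21 of 80 members rose, 0 fell and 59 did not pass by edgeR (1 lower at an unadjusted p under 0.05, 0 by DESeq2 and by limma-voom). It had 25 higher and 0 lower adjusted over the list alone, with adjusted p = 4.89e-09 and adjusted p = 0.363 with an estimated correlation. Of the 21, 17 are nuclear-encoded, such as ATP synthase subunit D (144661, 0.53 ± 0.076) and a nuclear control of ATP synthase model (67591, 0.58 ± 0.069), and 4 are mitochondrion-encoded. The share of reads matching several models was 0.365 ± 0.136% in the libraries titled root exudates and 0.155 ± 0.031% in their titled controls. Oxidative stress enzymes had 17 of 87 higher and 4 lower (adjusted over the list alone, 22 and 7; adjusted p = 0.0267, adjusted p = 0.319 with an estimated correlation). A glutathione S-transferase (343163) was at 1663 ± 153 against 874 ± 62.9 CPM and a thioredoxin h model (209220) at 1793 ± 187 against 998 ± 31.9 CPM.

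Of the single genes higher in the libraries titled root exudates, an ABC-2 type transporter (340002) was at 36.2 ± 7.87 against 1.01 ± 1.06 CPM (5.12 ± 0.468, and 7.02 and 4.35 without titled control replicate 1 or 2). A P-type ATPase of the heavy metal transporting type (32421) rose by 2.17 ± 0.202, and the aldo/keto reductases 33452 and 62569 by 2.05 ± 0.134 and 2.03 ± 0.158. A model of the macrophage migration inhibitory factor family (18774) rose by 2.88 ± 0.502, and by 3.61 without titled control replicate 1. Vesicle traffic genes had 21 of 192 higher and 9 lower (adjusted over the list alone, 21 and 10; adjusted p = 0.00358, adjusted p = 0.172 with an estimated correlation). Examples were the small GTPases 80188 (Rho3, 0.66 ± 0.098) and 336434 (Ras-like, 0.64 ± 0.097). Fatty acid beta-oxidation and peroxisome genes had 13 of 82 higher and 4 lower (adjusted over the list alone, 14 and 5; adjusted p = 0.0266, adjusted p = 0.220 with an estimated correlation). The peroxisomal docking factor Pex13 (343464) was at 0.68 ± 0.11 and isovaleryl-CoA dehydrogenase (40656) at 0.50 ± 0.09. Ribosomal protein genes had 18 of 166 higher and 7 lower by either adjustment (adjusted p = 0.0266, adjusted p = 0.605 with an estimated correlation), among them L36 (38814) at 0.40 ± 0.07.

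Lower in the libraries titled root exudates were most members of the high mobility group box list that passed, a family of DNA-binding proteins that includes fungal mating-type genes. In that list 32 of 128 fell, 6 rose and 90 did not pass (adjusted over the list alone, 35 and 10; adjusted p = 0.00586, adjusted p = 0.172 with an estimated correlation). The member 336521 had 2 reads against 1217, a ratio of 837 (95% interval 231 to 6920, counting error only), with a log2 change of -12.22 without titled root exudates replicate 2 and -8.855 without replicate 3. Of the other members, 85395 had 0 against 67 and was at least 30.8-fold lower, and 14969 changed by -3.69 ± 0.269. The chitin synthase model 67965 was at 0.224 ± 0.213 against 16.3 ± 9.76 CPM (-6.03 ± 0.654, and -6.72 without titled root exudates replicate 1 and -5.24 without titled control replicate 1). A C2H2 zinc finger model (50548) changed by -4.85 ± 0.309 and an HSP70-type model (23506) by -4.76 ± 0.342. Sugar and phosphate transporters had 5 of 25 lower and 1 higher (adjusted over the list alone, 6 and 2; adjusted p = 0.0416, adjusted p = 0.319 with an estimated correlation). The transporter 7986 was at 12.1 ± 2.56 against 54.7 ± 1.14 CPM. Protein kinases had 108 of 1195 lower and 61 higher (adjusted over the list alone, 105 and 61; adjusted p = 0.0230, adjusted p = 0.363 with an estimated correlation), among them 8278 at -1.18 ± 0.071. Sel1, BTB and kelch repeat proteins had 85 of 1071 lower and 29 higher (adjusted over the list alone, 67 and 25; adjusted p = 0.0126, adjusted p = 0.172 with an estimated correlation), among them 36113 at -1.53 ± 0.133. Over all 14752 models tested, 1144 were lower and 1101 higher. The share of lower calls among the repeat proteins was close to that, and their higher calls were fewer.

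By edgeR 2245 of 14752 models passed in the root comparison, 1101 higher and 1144 lower in the libraries titled root exudates, and of the 711 changed at least 2-fold (416 without titled control replicate 1) 563 were lower. The count was 1352 without titled root exudates replicate 2, 795 without titled control replicate 1 and 1106 without titled control replicate 2. In every fit that left out 1 library, 40 of the 50 named genes passed.

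Roots and GR24 at 14 d were then set side by side, to ask whether roots change the genes that the hormone changes. Across genes, which are not independent replicates, the root and GR24 log2 fold changes correlated with r = -0.1045 at 1 h, 0.0165 at 2 d, -0.1655 at 7 d and 0.0556 at 14 d. The value was -0.0654 at 1 h without titled control replicate 1 and -0.0909 at 7 d without GR24 replicate 3. At 14 d it was 0.01 without acetone replicate 3, 0.022 without GR24 replicate 1 and 0.0269 without titled control replicate 1. At 2 d it stayed within 1.5 times only without titled control replicate 2 (0.0207) among the fits leaving out 1 library, and turned without titled root exudates replicate 1 (-0.001) or acetone replicate 2 (-0.0199). At 14 d 37 models were higher in both comparisons (13.2 if calls were independent), 64 lower in both (18.6), 31 higher with GR24 but lower in the libraries titled root exudates (11.5) and 29 lower with GR24 but higher there (21.4). If the column headings are right, the 31 and 29 moved the same way in both comparisons and the 37 and 64 opposite ways. The difference between the root and GR24 effects at 14 d passed for 1749 of 15390 models, 984 of them more positive in the root comparison, and with the root direction of the column headings for 2068, 969 of them more positive. It passed for 560 models without the libraries of replicate 2 and 884 without replicate 3. The root libraries used index sequences that the time-course libraries also used, and the cultures, spore numbers and controls differed, so a difference between sequencing runs cannot be told apart from the difference between the sets.

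Of the genes chosen in advance for their role in symbiosis, an ammonium transporter (218287) passed in none of the 5 comparisons, with log2 fold changes from -0.20 to 0.19. The phosphate transporter 345640 rose at 1 h of GR24 by 0.475 ± 0.085 (adjusted p = 0.000589), and in the libraries titled root exudates it was at -0.715 ± 0.235 (adjusted p = 0.127). Another, 7378, was lower there (-1.015 ± 0.23, adjusted p = 0.0129), a call that ended without titled root exudates replicate 2 (-0.92) or titled control replicate 2 (-0.85). The phosphate transporter 22848 passed in none of the 5 comparisons, and 13201, a Pho84-like model, had too few reads to be tested. The tables used here name no gene SIS1, SP7 or MST2.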

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

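The tests of explanations for the root pattern and for the mitochondrial pattern were chosen only after the result was seen.

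Effects of GR24 differed between times by the interaction test for 1588 models (edgeR quasi-likelihood). With treatment labels redrawn within each time, only the real one of 100 splits called as many, 1 of 100, and the highest other called 1080. This argues against chance for this count but does not exclude it. The splits were a random draw of those possible, and some others also parted many models. For the shared effect of GR24 over the times, 1 of 100 splits, the real one, called 603 models and the highest other 265. This argues against chance there too, with the same limit. At 14 d the real split called 457 models and the highest other 5, 1 of 10 splits, which are too few for a share under 0.05.

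The root effect differed from the GR24 effect at 14 d for 1749 models, or for 2068 with the root direction of the column headings, and many genes that GR24 raised were lower in the libraries titled root exudates. Of the 98 models at least 2-fold higher with GR24 across times, 60 were tested in the root comparison, 28 of these were lower, 1 was higher, and their median log2 fold change was -1.252 (95% bootstrap interval -1.57 to -0.89). That interval was drawn over genes, which share the same libraries, so it leaves out the spread between libraries. Low counts or scaling alone are argued against, since with the strict filter and RLE size factors 10 of the 15 models tested were lower and 0 higher by edgeR. The median of -1.252 is what exchanged titles of the 2 root groups would give, and equally what roots lowering these genes would give, so this value leaves both open and the second otherwise untested. The deposited test of the authors, which follows the column headings, gave the opposite direction from the titles for all 878 models called by both, so the titles and the headings contradict each other.

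The share of gene reads matching several models was 0.798% with GR24 at 2 d, above the 0.374% of the acetone controls, as computed from the unique gene reads, a column outside the main tests. Beside it, 6 of 14 mitochondrion-encoded models were higher with GR24 at 2 d, with a median log2 fold change of 1.80. The 95% bootstrap interval of the median of the nuclear-encoded members, -0.042 to 0.089, was drawn over genes that share the same libraries. It therefore leaves out the spread between libraries. A rise of respiratory chain genes as a whole by a log2 of 0.5 or more is argued against by these members, whose median was 0.031, with 0 of 69 higher by edgeR, 16 at an unadjusted p under 0.05 and 0 by DESeq2 and limma-voom. Adjusted over the list alone, 8 of these 69 were higher, by 0.25 to 0.36 on the log2 scale, and 1 lower, so a small rise of some nuclear-encoded members stays open, and a change in the mitochondria themselves with GR24 stays untested. A candidate explanation is that RNA without poly-A tails carried over to a different extent between libraries. Over 25 libraries, as deviations from group means, the mitochondrion-encoded models and the 2 models with most multi-match reads correlated with r = 0.977 and rho = 0.985. The permutation p was 1e-05 for each, the smallest that 100000 permutations can give, and 1e-05 after Benjamini-Hochberg adjustment over both. Without the 2 farthest libraries r was 0.973. The 2 multi-match models have no description, so whether their RNA lacks poly-A tails is not known here. Group means were taken out, so the correlation does not bear on the difference between GR24 and acetone at 2 d. Nor does it tell carry-over from a change in the mitochondria.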

How the results depend on the processing

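The exclusion of models carrying multi-match and mitochondrial reads, the corrected lists and the root direction of the column headings were chosen only after the data were seen. Values for single genes, for the gene lists that passed and for the correlation at single times were counted together, once per alternative. Of these, 2231 kept their direction and side of the threshold under the alternatives chosen in advance and 173 under the added exclusion, while 201 kept their direction but no longer passed, 12 moved beyond their spread and 3 turned. RLE size factors and the strict filter left every count of models past an adjusted p of 0.05 within 1.5 times its value, as did limma-voom, unique gene reads and the added exclusion for the 5 treatment comparisons they were run on. With the root direction of the column headings, the root effect minus the GR24 effect passed for 2068 models, 946 of them also among the 1749, where 934 had the opposite sign. With corrected lists 33 list tests passed. Of models that also changed at least 2-fold, the strict filter, which leaves out models with few reads, gave 176 at 1 h, 42 at 2 d, 213 at 7 d, 36 at 14 d, 398 in the root comparison, 33 across times and 1763 in the controls over time, each over 1.5 times fewer, and DESeq2 gave 216 at 7 d. Without a filter on low counts these numbered 163 at 2 d and 117 at 14 d, and with all libraries in 1 fit 133 at 2 d. Without a filter on low counts, 831 models passed at 2 d and 863 at 14 d, where more models were tested. With the replicate number as a block, 504 passed at 2 d, and that model could not be fitted at 7 d, where no residual degrees of freedom remain. With all libraries in 1 fit, 748 passed at 2 d and 3434 in the root comparison. DESeq2 gave 500 at 7 d. The shared GR24 effect passed for 308 models without the 7 d libraries and for 396 without the 14 d libraries, but for 505 without 2 d and for 837 without 1 h (366 higher and 471 lower, 399 shared with the 603). With an estimated correlation, 0 lists passed. The correlation across genes of root and GR24 effects at 14 d was 0.0979 among models with a mean of at least 50 reads, and that with the 2 d effects turned to -0.0046 there and to -0.001 without titled root exudates replicate 1. Apart from more tested models where stated, the cause was not tested. Fits leaving out 1 library gave 689 to 1418 models at 1 h, 46 to 457 at 2 d, 574 to 1315 at 7 d, 250 to 513 at 14 d and 795 to 2919 for roots. Leaving out 1 replicate number gave 144 to 296 for the shared effect, 395 to 1313 for the interaction, 6207 to 7835 for the controls over time and 560 to 1372 for the root effect minus the GR24 effect. The correlation at 14 d ran from 0.01 (without acetone replicate 3) to 0.0763, that at 2 d from -0.0199 (without acetone replicate 2) to 0.0415, that at 1 h from -0.1319 to -0.0654 (without titled control replicate 1) and that at 7 d from -0.1814 to -0.0909 (without GR24 replicate 3). By Spearman's method the value was -0.0336 at 1 h and 0.062 at 2 d. Changes below 2-fold were partly out of reach at this depth and these group sizes, since in simulated data edgeR recovered 37.3% to 79.1% of genes changed 1.5-fold, and 91% for the shared effect. Those simulated changes were placed only in genes with a mean of at least 5 CPM.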

Other observations

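The tests of genes raised at 1 h and lowered at 14 d, of corrected lists, of lists in the acetone controls, of the change from 2 d to 14 d in histones and cell cycle genes and of levels of root-set genes were chosen only after the results were seen.

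Some detoxification genes went in opposite directions early and late. Of the models that GR24 raised at 1 h, 73 were lower at 14 d, where 18.4 would be if calls were independent. Calls also overlapped in the other directions, with 30 higher at both times (11.9 if independent), 23 lower at both (9.4) and 20 lower at 1 h and higher at 14 d (6). The 73 became 30 without GR24 14 d replicate 1, 33 without acetone 14 d replicate 3, 41 without acetone 14 d replicate 2 and 38 without acetone 1 h replicate 3, and 11 of them kept both calls in every fit leaving out 1 library. Among these 11, the ABC-2 type transporter 22144 was at 2.86 ± 0.153 on the log2 scale at 1 h and -1.49 ± 0.186 at 14 d (interaction adjusted p = 2.09e-10), the P450 model 36234 at 1.10 ± 0.08 and -0.45 ± 0.078 (interaction adjusted p = 1.49e-10), and the P450 model 317811 at 0.61 ± 0.07 and -0.45 ± 0.044 (interaction adjusted p = 2.82e-10). These genes were named after their values were seen. Among members of the P450 and glutathione S-transferase list raised at 1 h, 12 of 49 were lower at 14 d against 3.9 expected (Fisher's exact test, p = 2e-04, adjusted p = 0.00638 over 32 lists), and among the ABC and multidrug transporters 6 of 30 against 2.4 (adjusted p = 0.4). Fisher's test counts genes as independent draws, which genes of the same libraries are not, so its p-values leave out the spread between libraries.

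As the acetone controls aged from 1 h to 14 d, most cytosolic ribosomal protein genes that passed the test fell. In the cytosolic ribosomal protein list 97 of 167 members fell and 20 rose (21 higher and 97 lower adjusted over the list alone; adjusted p = 1.20e-11, adjusted p = 0.256 with an estimated correlation). Of the 78 members described as 40S or 60S ribosomal proteins, 71 fell and 3 rose (adjusted p = 3.64e-30, adjusted p = 0.172 with an estimated correlation). Translation factors and tRNA synthetases had 102 of 211 lower and 47 higher (adjusted p = 0.0597), and ribosome biogenesis 60 of 153 lower and 38 higher (adjusted p = 0.367). Without their unintended members these lists passed downwards, at adjusted p = 0.00216 and 0.00268, and adjusted p = 0.315 and 0.549 with an estimated correlation. Nuclear-encoded members of oxidative phosphorylation had 30 of 69 lower and 10 higher, and 0 of 14 mitochondrion-encoded models passed by edgeR, with 1 higher at an unadjusted p under 0.05 and 0 by DESeq2. Trehalose and glycogen genes had 11 of 18 higher and 3 lower, with an adjusted p of 0.0869 for the list.

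The histones and cell cycle genes raised by GR24 at 7 d were weighed further, with 56 called members and a median log2 fold change of 0.983. Reads shared between near-identical copies are argued against, since 100% of these members stayed past the threshold with unique gene reads. A single deciding library is argued against for these members, since their lowest median in a fit leaving out 1 library was 92.5% of the full one. They were chosen by their calls with all libraries, which favours members whose libraries agree, so this check does not cover the other list members. With 2 libraries per group at 7 d, it also cannot show how far libraries of a group spread. In the 3 acetone libraries at 2 d, histone H4 (29938) was at 183, 316 and 232 CPM. The ribonucleotide reductase small subunit (80358) was at 67.3, 131 and 96.6 CPM there. In the acetone libraries at 14 d they were at 63.0, 62.2 and 50.5 CPM and at 10.8, 12.8 and 9.06 CPM. A candidate explanation is that GR24 shifts when nuclei divide: in acetone controls the same members changed by a median of -0.847 from 2 d to 7 d, a value that shares its 7 d libraries with the pattern, while with GR24 they changed by -0.092. From 2 d to 14 d, which shares no 7 d library, the controls changed by -1.84, whereas over all tested members of the lists the change from 2 d to 7 d was -0.154. At 14 d the GR24 effect on these members had a median of -0.005, and in the libraries titled root exudates it was -0.341, with 13 lower.

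Genes much lower in the libraries titled root exudates, a set that by its choice was high in the titled controls, were also compared with the time course. The 179 models at least 4-fold lower had a median of 0.838 CPM, against 6.54 in the titled controls. In the 8 time-course groups their medians ran from 0.742 CPM (acetone 7 d) to 1.94 CPM (GR24 2 d), and 42 of them lay under 0.5 CPM in all 8. The 28 models at least 4-fold higher, by their choice low in the titled controls, had a median of 4.33 against 0.924 CPM there, and medians from 1.89 CPM (acetone 1 h) to 6.35 CPM (acetone 7 d) in the time course.

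Results of the lists whose keywords drew in unintended members are given as values. The crinkler and secreted effector list, mostly HSP70 chaperones, was lower at 1 h (9 of 156 lower, 2 higher, adjusted p = 0.0274, adjusted p = 0.347 with an estimated correlation), at 2 d (3 of 160 lower, adjusted p = 0.0203, adjusted p = 0.273 with an estimated correlation) and across times (12 of 166 lower, adjusted p = 0.00628, adjusted p = 0.122 with an estimated correlation). It was also lower in the libraries titled root exudates (34 of 173 lower, 7 higher, adjusted p = 0.00358, adjusted p = 0.172 with an estimated correlation), where the HSP70-type model 342089 was at 366 ± 42.1 against 964 ± 2.58 CPM. Adjusted over the list alone, the lower members numbered 7, 3, 16 and 36 in these 4 comparisons. The 41 members left at 1 h and in the root comparison without the HSP70 models had adjusted p values of 0.749 and 0.613. In the root comparison the cytoskeleton list had 41 of 745 higher and 61 lower (adjusted p = 0.117). After correction the balance turned, with 29 of 285 higher and 15 lower (adjusted p = 0.283). The non-fungal keyword list had 9 of 101 higher and 14 lower (adjusted p = 0.595), and after correction 4 of 37 higher and 3 lower (adjusted p = 0.474). The ribosome biogenesis list across times had 5 of 154 higher and 2 lower (adjusted p = 0.333). Its 83 members after correction passed downwards across times (adjusted p = 0.0387, adjusted p = 0.820 with an estimated correlation) and at 2 d (adjusted p = 0.0461, adjusted p = 0.6615 with an estimated correlation). By edgeR 0 of the 83 were called in both, with 7 and 13 lower and 3 and 4 higher at an unadjusted p under 0.05, while DESeq2 called 1 lower across times and 0 at 2 d, and limma-voom 0 at 2 d. The translation factor list at 1 h had 11 of 203 higher and 6 lower (adjusted p = 0.233). In the cytosolic ribosomal protein list the 78 members described as 40S or 60S ribosomal proteins had 2 higher and 0 lower at 2 d by edgeR, DESeq2 and limma-voom (1 lower by edgeR at an unadjusted p under 0.05; adjusted p = 8.54e-06, adjusted p = 0.552 with an estimated correlation). They had 11 higher and 1 lower in the libraries titled root exudates (adjusted p = 0.00849, adjusted p = 0.589 with an estimated correlation). Across times the 78 passed upwards (adjusted p = 0.00773, adjusted p = 0.820 with an estimated correlation) with 0 called by edgeR and by DESeq2, and 9 higher by edgeR at an unadjusted p under 0.05.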
